A study of Mus musculus with 6 samples.

How the data were processed

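The series measured messenger RNA by sequencing of pancreatic islets, the clusters of hormone-secreting cells of the pancreas, from wild-type mice (WT) and from mice with a beta-cell-specific transgene for the microRNA miR-203 (TG). Per the labels, all mice were male, 10 weeks old and fasted for 12 h. The islets were frozen in liquid nitrogen, RNA was extracted with TRIZOL, and 3 µg of RNA per sample entered a NEBNext Ultra library kit. There were 3 WT and 3 TG libraries, numbered here within each genotype. The labels place WT 1, WT 2, TG 1 and TG 2 in 1 set of tables (the first table) and WT 3 and TG 3 in another (the second table), so the table was treated as a batch that holds both genotypes. The labels do not state that the libraries came from separate animals, so all p-values measure the spread between these samples, which may be partly technical.

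CASAVA 1.8, HISAT2 and the mouse genome build GRCm38 (mm10) are named in the submitters' processing notes. The read counter, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be told apart and such genes are uncertain. The deposited raw counts were whole numbers for 47643 genes in each table, and 29725 genes had a count in any library. The authors also deposited a normalized signal per gene. Each of its values was close to the raw count times 1 factor per library, with a median factor between 0.819 in TG 1 and 1.26 in WT 1, and it was made separately for the 2 tables. The deposited FPKM values were scaled from that signal by gene length, per the file headers and the values themselves. The signal and the FPKM served only to check what the files hold, and the gene names, chromosomes, starts and ends came from the authors' annotated FPKM tables. All results below were computed from the raw counts.

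Total counts were 20176456, 24631199 and 21136559 in WT 1, WT 2 and WT 3, and 27110459, 27482339 and 21615905 in TG 1, TG 2 and TG 3. At these depths, the widest 95% Wilson interval of a share of reads reached 0.0186 percentage points to either side for the summed islet hormones, 0.0153 for Ins2 and 0.00363 for the acinar genes. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 was taken to allow up to 3 counts, converted to CPM per library. No row lacked a gene, and no pair of libraries had counts that matched within sampling noise. The closest pair, WT 1 and TG 2, had a chi-square of 31.6 per degree of freedom over 13065 genes with a count of at least 20 in every library.

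Counts of both tables were joined on the gene identifier and fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr by genotype, TMM normalization, quasi-likelihood F-test, robust estimation off), with the table and the genotype as terms. Of the genes, 16072 passed the filter, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are CPM, read counts scaled to the TMM-adjusted library size, given as means ± SD over the 3 libraries of a genotype. Log2 fold changes are TG over WT. Their standard error (SE) was derived from the F-test, as the absolute log2 fold change divided by the square root of F. Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2. Lists with under 5 tested genes were only described. The difference of the TG effect between the tables was tested as the interaction of table and genotype. The second table holds 1 library of each genotype, so this test borrows the spread of the first table's libraries, and a fit that leaves a genotype with 1 library in a table assumes that this library varies like the others.

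The tests, the samples and covariates of each, the processing alternatives, 31 gene lists and the rule for named genes were chosen before the data were examined. The lists covered beta-cell hormones and transcription factors, glucose sensing and insulin secretion, exocytosis machinery, alpha-cell markers, delta- and PP-cell markers, beta-cell disallowed and dedifferentiation genes, beta-cell compensation and proliferation regulators, and mitotic cell cycle. They also covered ER stress, apoptosis and p53 targets, oxidative stress, mitochondrial respiratory chain, glycolysis, cholesterol and fatty-acid synthesis, and cytosolic ribosomal proteins. Others held genes of interferon response, NF-kB and inflammatory signalling, immediate-early genes, hypoxia, circadian clock, extracellular matrix, reported miR-203 targets in other tissues, and markers of acinar, duct, endothelial, stellate, myeloid, lymphoid, Schwann, fat and red blood cells. The rule named the Mir203 gene, Ins1, Ins2, Iapp, Gcg, Sst and Ppy. It then took, per direction, the 10 genes with the largest change among those past the threshold, and the 5 most abundant called genes. The former needed a mean CPM of at least 5 and every TG library on the same side of every WT library of its own table. Where fewer than 10 passed, the genes of smallest p filled the 10 and are named as not past the threshold. Of each list, at most 4 members were named in order of smallest p. Some list members that the rule names are not reported here. Besides the sex-linked genes and the neighbours of Mir203, given as checks, Mafa, Slc2a2, Cck, Nkx6-1, Sox9 and, from lists drawn up later, Npy, Nts, Cartpt, Fgb, Cpb2 and Alb were named outside the rule, after their values were seen.

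Sites for miR-203-3p were searched in the annotated 3' untranslated region (3' UTR) of GENCODE M21 transcripts, a gene annotation on GRCm38, using the longest 3' UTR of each of 21037 genes. A site was the 7-mer CATTTCA, which pairs with positions 2 to 8 of the mature microRNA. The mean log2 fold change of tested genes with a site minus that of tested genes without was set against the same difference for all 210 rearrangements of these 7 bases, the site itself among them, and against all 7-mers found in at least 100 genes. Genes are not replicates, so the difference was ranked among motifs and not tested across genes. The share of rearrangements with a difference as low is given as a one-sided permutation p. It does not measure the spread between libraries. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for these steps and the figures.

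The edgeR tests, camera on the genotype and the site tests were tested on simulated data with known answers. Over 5 draws of counts for the 16072 genes, with 200 genes changed in each, the edgeR test recovered 29.6% of 2-fold, 80.3% of 4-fold and 93.9% of 8-fold changes. Of its 750 calls, 9.6% were false, above the nominal share. Each simulated change was equal in all 3 TG libraries, so these shares do not hold for changes that TG 2 shares little. Gast, with a log2 fold change of 10.1 in the data, had an adjusted p of 0.199 in edgeR. In the same simulated draws camera called 5 of 5 raised sets and 0 untouched sets at an unadjusted p under 0.05. Genes were drawn independently of each other, so these draws cannot show how camera behaves where genes vary together. In the lists past camera below, the estimated correlation ran from -0.05 (clock) to 0.80 (matrix). In the site search, a simulated shift of 0.1 in site genes gave a mean difference of -0.0997 and the lowest value of all 210 arrangements in 10 of 10 draws, and no shift gave the lowest in 0 of 10. Simulations of the interaction and of the site share were added after the results were seen. With 200 genes changed in TG 3 alone, the edgeR interaction over 16072 genes recovered 0% of 2-fold, 16.7% of 4-fold and 58.2% of 8-fold changes in 5 draws, and 21.3% of its 315 calls were false. In the site-share test, lowering 10% of the site genes gave a mean difference of 21.45 percentage points. The site ranked highest of all 210 arrangements in 10 of 10 draws. With shuffled values alone it did so in 0 of 10 and came within the highest 5% in 1 of 10. Both simulated site effects were larger than the observed differences of -0.0171 and 4.72 points, and values were shuffled over genes. The simulations thus do not show what these tests detect at the observed size. The camera test of the interaction and the checks for mixed or carried-over RNA were not simulated.

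The alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter of CPM of at least 1 in 3 libraries, no table term, the first table only, each library left out in turn, the acinar marker level as a covariate, and hormone and acinar genes left out of the library sizes. For lists they included an estimated correlation and fry, and for sites the 8-mer, any 6-mer, the shortest 3' UTR, a minimum CPM of 5 and an adjustment for 3' UTR length and GC content. Voom with library weights, edgeR without the low-count filter in its bias-adjusted form, and the share of site genes among lower and higher genes with its own alternatives were added after the data were seen.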

Results

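Gene expression was profiled by RNA sequencing in islets of WT mice and of TG mice, which carry a transgene for miR-203 in their beta cells, to find which genes differ between the genotypes. Each genotype had 3 libraries, with 20176456 to 27482339 counts per library, of which WT 1, WT 2, TG 1 and TG 2 were deposited in the first table and WT 3 and TG 3 in the second. The islet hormone genes Ins1, Ins2, Iapp, Gcg, Sst, Ppy and Pyy together took 23.9%, 24.2% and 15.8% of counts in WT 1, WT 2 and WT 3, and 13.4%, 24.0% and 12.3% in TG 1, TG 2 and TG 3. Acinar genes, which mark the enzyme-secreting tissue around islets, took 0.396%, 0.853% and 0.0238% in the WT libraries and 0.519%, 0.601% and 0.0470% in the TG libraries. The second table thus held less acinar RNA in both genotypes. The libraries also parted by sex-linked transcripts, although all were labelled male. Xist, the RNA that silences an X chromosome in female cells, had 13, 4, 12 and 8 counts in WT 1, WT 2, TG 1 and TG 2, against 25145 in WT 3 and 27240 in TG 3. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had between 5463 and 7468 counts in the first table's libraries, 16 in WT 3 and 1 in TG 3. This difference follows the table and not the genotype, and the table was a term of every comparison unless stated.

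The Mir203 locus was examined first, because its reads check the genotype labels. Mir203 (ENSMUSG00000065574) lies on chromosome 12 at 112130880 to 112130955 of GRCm38, on the plus strand. The 76-base microRNA gene overlapped 0 other annotated genes and sat between Aspg, which ends at 112127559, and Kif26a, which starts at 112146208. The mature sequence GTGAAATGTTTAGGACCACTAG, given here as DNA, occupied bases 112130927 to 112130948. All 3 TG libraries carried reads there, with 170, 164 and 150 counts in TG 1, TG 2 and TG 3. These were 5.91 CPM (95% exact Poisson interval 5.06 to 6.87), 6.51 CPM (5.55 to 7.59) and 6.23 CPM (5.27 to 7.31). WT 2 and WT 3 had 0 counts, which allow up to 0.132 and 0.131 CPM. The library labelled WT 1 had 39 counts, or 2.11 CPM (1.5 to 2.88). The group means were 6.22 ± 0.30 CPM in TG and 0.702 ± 1.22 CPM in WT (SD, n = 3). The fitted log2 fold change of 3.49 (SE 1.28) depends on the prior count used for libraries at 0, and it did not pass the threshold in edgeR (Benjamini-Hochberg adjusted p = 0.301). With each library left out in turn it ran from 2.59 (without WT 3) to 10.27 (without WT 1, the WT library with reads). The adjusted p of the Mir203 locus ran from 7.81e-16 without the low-count filter to 0.966 with the first table only. No small-RNA library was analysed here, and the level of the 22-base mature microRNA was not measured.

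**Figure D1:**
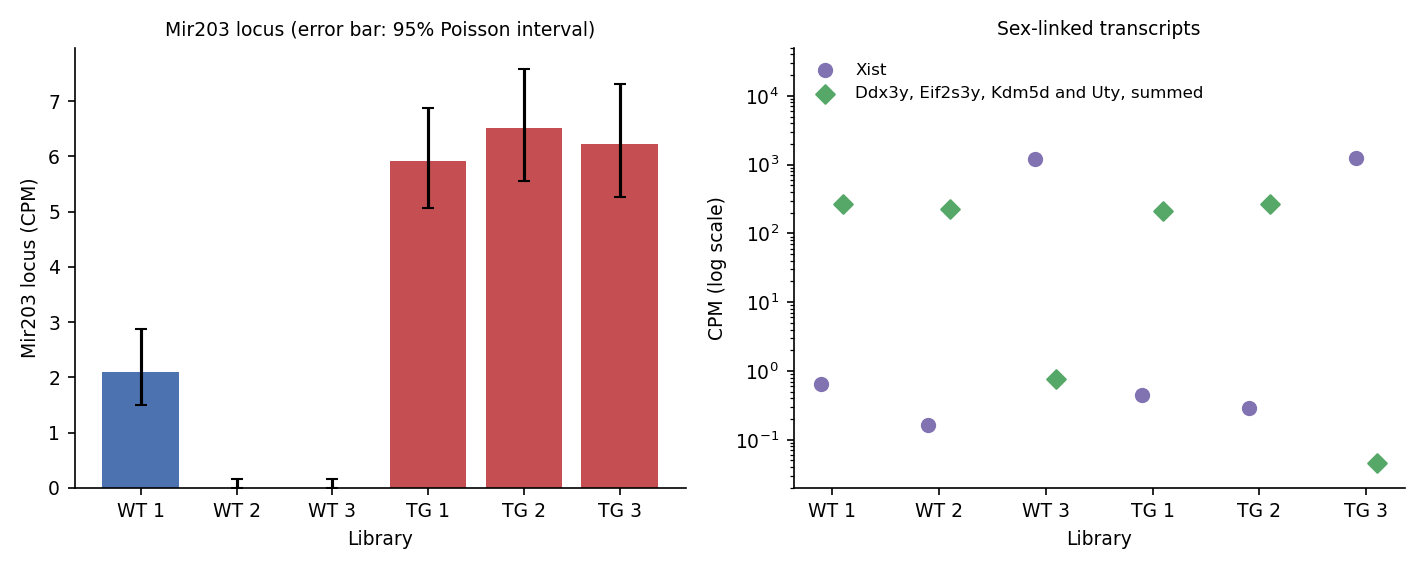
Left, CPM at the Mir203 locus in each library, with 95% exact Poisson intervals as error bars; the TG libraries lie between 5.91 and 6.51 CPM, WT 1 at 2.11 CPM and WT 2 and WT 3 at 0. Right, CPM (log scale) of Xist as circles and of 4 Y-linked genes summed as diamonds, with Xist high and the Y-linked genes near 0 in WT 3 and TG 3, the libraries of the second table.

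Insulin transcripts were lower in each TG library than in the WT libraries of its own table, and most in TG 1 and TG 3. Ins2, the main mouse insulin gene (chromosome 7, 142678656 to 142699510), made up 14.4%, 15.5% and 8.57% of counts in WT 1, WT 2 and WT 3, but 2.47% in TG 1 and 3.04% in TG 3, while TG 2 held 13.7%. Ins1 (chromosome 19, 52264323 to 52265456) averaged 9931 ± 5405 CPM in TG and 20107 ± 5961 CPM in WT (SD, n = 3) and was below the WT libraries of its own table in every TG library. Ppy, the hormone of PP cells, was at 13989 ± 6006 CPM in TG and 4174 ± 994 CPM in WT. Glucagon (Gcg), somatostatin (Sst) and Iapp, the amyloid peptide secreted with insulin, differed less, with log2 fold changes of 0.44 (SE 0.37), 0.52 (SE 0.30) and -0.16 (SE 0.38). The log2 fold changes were -1.12 (SE 0.65) for Ins2, -1.01 (SE 0.35) for Ins1 and 1.70 (SE 0.40) for Ppy. None of these hormone genes passed the threshold in edgeR, with Benjamini-Hochberg adjusted p of 0.478, 0.285 and 0.204 for Ins2, Ins1 and Ppy and 0.627, 0.478 and 0.884 for Gcg, Sst and Iapp. The calls turned on TG 2. Without it edgeR gave log2 fold changes of -2.25 for Ins2 (adjusted p = 0.0208), -1.43 for Ins1 (0.0250) and 2.05 for Ppy (0.0108). Over all alternatives the adjusted p ran from 0.00273 to 0.9997 for Ins2, from 0.00225 to 0.979 for Ins1 and from 1.24e-08 to 0.924 for Ppy, each lowest without the low-count filter. DESeq2 called Ins1 (0.0320). Gcg, Sst and Iapp passed under none of the alternatives. The fitted Iapp value was above 0 without WT 1 (0.05) and without TG 1 (0.11).

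Mafa and Ucn3 were far lower in TG 1 and TG 3 than in WT, with TG 2 in between. Mafa, a transcription factor that drives insulin transcription, was at 406, 487 and 675 CPM in WT 1, WT 2 and WT 3, and at 3.72, 249 and 18.1 CPM in TG 1, TG 2 and TG 3. Ucn3, a peptide of mature beta cells, was at 215, 271 and 380 CPM in the WT libraries and at 3.03, 139 and 4.73 CPM in the TG libraries. Slc2a2, which encodes the glucose transporter GLUT2, averaged 98.0 ± 74.8 CPM in TG and 299 ± 63.5 CPM in WT, and Mafa and Slc2a2 were named after their values were seen. Pdx1, a transcription factor required for beta-cell identity (chromosome 5, 147269959 to 147275848), was less scattered, at 85.8 ± 10.5 CPM in TG and 142 ± 1.30 CPM in WT (SD, n = 3), and its log2 fold change was -0.73 (SE 0.14). Their adjusted p over all genes were 0.410 for Mafa, 0.410 for Ucn3, 0.246 for Slc2a2 and 0.199 for Pdx1 (edgeR, Benjamini-Hochberg). Without TG 2 all 4 passed in edgeR, with log2 fold changes of -6.10 for Mafa (adjusted p = 0.00104), -6.33 for Ucn3 (8.79e-05), -2.45 for Slc2a2 (0.00533) and -0.79 for Pdx1 (0.0152). DESeq2 called Slc2a2 (0.0135) and Pdx1 (0.000894) but not Mafa (0.376) or Ucn3 (0.348). Over all alternatives the adjusted p ran from 1.45e-29 to 0.9997 for Mafa, from 7.04e-34 to 0.9997 for Ucn3, from 3.64e-13 to 0.936 for Slc2a2 and from 0.000894 to 0.924 for Pdx1. The lowest came from edgeR without the low-count filter for Mafa, Ucn3 and Slc2a2, and from DESeq2 for Pdx1. The bias-adjusted form of edgeR on the same unfiltered genes called 0 genes. Of the 18 beta-cell hormones and transcription factors, 9 were higher and 9 lower in TG, and Pdx1 was the 1 past the threshold when adjusted over the list alone (adjusted p = 0.0217). As a set the list did not pass camera (adjusted p = 0.377), and its median log2 fold change of 0.02 and its mean of -0.41 differed in sign, with camera's direction down.

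**Figure D2:**
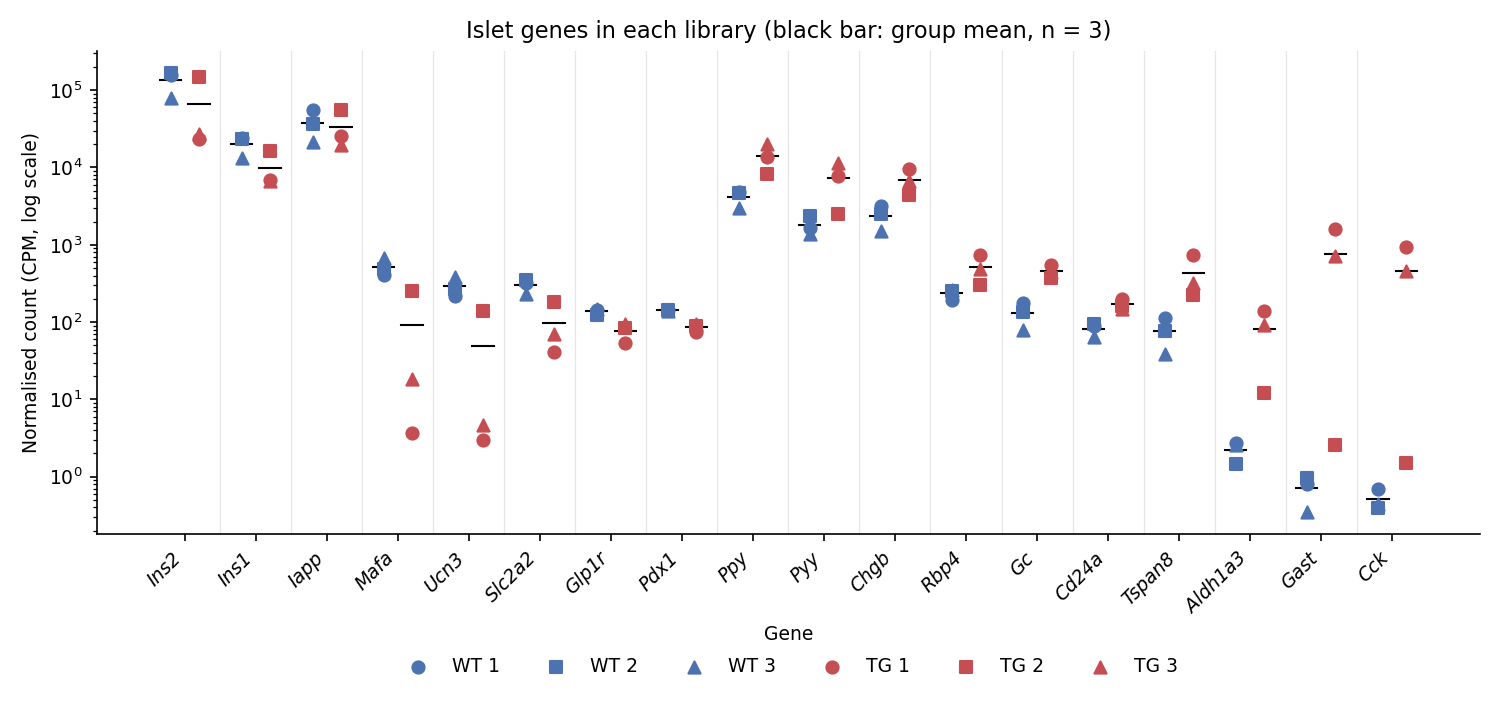
CPM (log scale) of 18 islet genes in each library, WT in blue and TG in red, with the mean of the 3 libraries as a black bar. For Ins2, Mafa, Ucn3, Gast and Cck, TG 1 and TG 3 lie apart from the WT libraries and TG 2 lies near them. Pdx1 and Glp1r are lower, and Gc and Cd24a higher, in all 3 TG libraries than in the WT libraries of their table.

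Among all genes, those with the smallest p and higher levels in TG included Actn2, a muscle-type actinin, Kcnip2, a potassium channel subunit, Selp, the adhesion receptor P-selectin, Gc, the vitamin D binding protein, and Cd24a, a surface glycoprotein. Gc was at 453 ± 83.6 CPM in TG and 130 ± 48.5 CPM in WT, and Cd24a at 169 ± 28.5 and 82.3 ± 15.8 CPM. Kcnip2 was at 2.89 ± 0.768 CPM in TG and 0.378 ± 0.0466 CPM in WT, Selp at 3.57 ± 0.790 and 0.337 ± 0.184 CPM, and Actn2 at 5.62 ± 3.27 and 0.662 ± 0.428 CPM (SD, n = 3). Sprr1a, Spon2, Ros1 and Dse completed the higher genes with log2 fold changes of 1.83, 1.07, 3.87 and 1.37. Clrn3, the tenth, was at 3.30, 1.03 and 6.10 CPM in TG 1, TG 2 and TG 3 and at or below 0.108 CPM in the WT libraries, under the floor of 3 counts. Among the lower genes, Phactr1, an actin regulator, was at 81.7 ± 20.2 CPM in TG and 177 ± 19.0 CPM in WT, and Robo1, an axon guidance receptor, at 25.2 ± 1.02 and 44.5 ± 9.28 CPM. Vps8, a vesicle tethering factor, was at 38.2 ± 8.54 and 72.1 ± 4.25 CPM, and Wdr7 at 56.5 ± 1.48 and 87.5 ± 7.86 CPM. The other lower genes were Pdx1, Cnnm1, Rnf157, Srgap1, Slc35b4 and B630019K06Rik. The log2 fold changes of the 10 lower genes lay between -1.48 (Cnnm1) and -0.63 (Wdr7).

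None of these 20 genes passed the threshold in edgeR or in limma-voom, whereas all 20 passed in DESeq2, in edgeR without TG 2 and in edgeR without the low-count filter. The edgeR test called 0 of 16072 genes at a Benjamini-Hochberg adjusted p under 0.05, with 0.199 as the smallest, while 1498 genes were higher and 773 lower at an unadjusted p under 0.05. DESeq2 called 616 higher and 136 lower, and limma-voom called 0, with 1363 higher and 872 lower at an unadjusted p under 0.05. The edgeR test without the low-count filter called 1300 higher and 372 lower, and its bias-adjusted form without that filter called 0, with 2035 higher and 971 lower at an unadjusted p under 0.05. The count depended on TG 2, since without it edgeR called 1461 genes higher and 727 lower, and every other library left out gave 0. Every TG library lay above the WT libraries of its own table in 2090 genes (13.0%) and below them in 2156 genes (13.4%), where chance gives 8.33% in each direction. Across genes, which are not independent replicates, the log2 fold changes of the first and the second table had r = 0.643 and the same sign in 70.2% of genes.

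Genes that beta cells normally keep silent or that mark their dedifferentiation rose as a list in TG by camera with its preset correlation. Of the 23 genes, 21 were higher, and 9 passed when adjusted over the list alone. Over all genes 0 passed in edgeR, with 15 at an unadjusted p under 0.05, and 0 in limma-voom, against 9 in DESeq2 and 15 in edgeR without TG 2. Aldh1a3, a retinaldehyde dehydrogenase that marks failing beta cells (chromosome 7, 66390890 to 66427517), was at 139, 12.0 and 91.5 CPM in TG 1, TG 2 and TG 3 and at 2.24 ± 0.689 CPM in WT. Gast, the gut hormone gastrin (chromosome 11, 100334407 to 100336996), reached 1603 CPM in TG 1 and 705 CPM in TG 3, but 2.58 CPM in TG 2, against 0.709 ± 0.321 CPM in WT (SD, n = 3). Igfbp4 and Serpina7 had log2 fold changes of 1.40 (SE 0.25) and 1.31 (SE 0.27). The median member lay 1.63, 0.41 and 1.04 log2 units above the WT level of its table in TG 1, TG 2 and TG 3. The camera adjusted p was 1.57e-07, and with an estimated correlation it was 0.776 (unadjusted 0.158). At the preset correlation the list stayed past the camera threshold whichever library was left out (highest adjusted p 0.000168). It shares 1 gene each with the duct (Sox9), stellate (Pdgfra) and hypoxia (Hk2) lists, which also rose.

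Markers of the other endocrine cells rose as lists too by camera with its preset correlation, mostly through TG 1. The median gene lay 0.89, 0.18 and 0.24 log2 units from the WT level of its table in TG 1, TG 2 and TG 3 for delta and PP cells and 0.87, 0.07 and 0.13 for alpha cells, with WT 2 at 0.20 and 0.24. All 9 delta- and PP-cell genes had higher fitted values in TG, with Ppy, Pyy and Rbp4 among those past the threshold when adjusted over the list alone. Pyy, a peptide of the same family as Ppy, was at 7850, 2522 and 11318 CPM in TG 1, TG 2 and TG 3 and at 1788 ± 498 CPM in WT (SD, n = 3). Of the 14 alpha-cell genes 12 were higher, and Tmem27, Gria3 and Ttr passed when adjusted over the list alone, with log2 fold changes of 1.33 (SE 0.25), 1.52 (SE 0.31) and 0.67 (SE 0.19), whereas Slc7a2 had a log2 fold change of -0.35 (SE 0.15). The camera adjusted p was 0.0104 for the delta- and PP-cell list and 0.0423 for the alpha-cell list. With an estimated correlation it was 0.776 and 0.838 (unadjusted 0.179 and 0.423). Over all genes 0 members passed in edgeR or limma-voom, with 4 delta- and PP-cell and 4 alpha-cell genes at an unadjusted p under 0.05 in edgeR. DESeq2 called 1 and 3 members, and edgeR without TG 2 called 4 and 2. Without TG 1 the adjusted p at the preset correlation was 0.0534 and 0.465, and without WT 1 that of the alpha-cell list was 0.330. With the acinar covariate that of the alpha-cell markers was 0.0523.

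Genes of glucose sensing and insulin secretion fell as a list by camera with its preset correlation. Of the 25 genes, 19 were lower, among them Glp1r, the receptor of the incretin GLP-1 (chromosome 17, 30901867 to 30936510), at 76.8 ± 20.6 CPM in TG and 139 ± 13.8 CPM in WT, and Pcx, pyruvate carboxylase, at 63.9 ± 31.1 and 165 ± 45.7 CPM (SD, n = 3). Chgb (chromogranin B) and Scg5 were higher, with Chgb at 6874 ± 2528 CPM in TG and 2391 ± 846 CPM in WT, and Scg5 at 1526 ± 218 and 969 ± 299 CPM. Glp1r and Chgb passed when adjusted over the list alone, and Scg5 did not (0.0571). Over all genes 0 members passed in edgeR, with 3 higher and 9 lower at an unadjusted p under 0.05, and 0 in limma-voom. DESeq2 called 8 members and edgeR without TG 2 called 12. The camera adjusted p was 0.0104, and with an estimated correlation it was 0.838 (unadjusted 0.286). Without WT 1 the adjusted p at the preset correlation was 0.0670.

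Markers of duct, Schwann and stellate cells and extracellular matrix genes rose as lists in TG by camera with its preset correlation, and endothelial markers did so through TG 3. None of these 5 lists passed with an estimated correlation (adjusted p 0.776 or higher). All 12 duct-cell genes were higher, led by Spp1 (osteopontin) at 502 ± 127 CPM in TG and 183 ± 104 CPM in WT and Tspan8 at 429 ± 276 and 76.2 ± 37.7 CPM (SD, n = 3). Spp1, Tspan8, Ambp and Muc1 passed when adjusted over the list alone. Of the 8 Schwann-cell genes 7 were higher, with Sox10 and Cdh19 among those past the threshold when adjusted over the list alone and log2 fold changes of 1.37 (SE 0.35) and 1.58 (SE 0.48). Of 22 extracellular matrix genes 21 were higher, with Timp1 at 71.2, 5.56 and 11.8 CPM in TG 1, TG 2 and TG 3 and 2.82 ± 0.559 CPM in WT. Of 15 stellate-cell genes, 5 of which are also in the matrix list, 12 were higher. Of 14 endothelial genes 12 were higher, with Vwf at 6.27 ± 3.02 CPM in TG and 2.21 ± 1.24 CPM in WT. The median gene lay 0.58, 0.29 and 1.02 log2 units from the WT level of its table in TG 1, TG 2 and TG 3 for duct and 1.30, 0.39 and 1.04 for Schwann cells. It lay at 2.38, -0.19 and 0.99 for matrix, at 1.39, -0.58 and 1.21 for stellate cells and at -0.04, -0.11 and 1.12 for endothelial cells. For these last 3 lists TG 2 lay between WT 1 (-0.52, -0.60 and -0.22) and WT 2 (0.52, 0.60 and 0.22). Over all genes 0 members of these lists passed in edgeR or limma-voom. At an unadjusted p under 0.05 edgeR had 5 duct, 4 Schwann, 7 matrix, 5 stellate and 2 endothelial genes. Among all genes 2271 of 16072 had such a p, and the endothelial share was near that background. In the same order DESeq2 called 4, 1, 2, 2 and 1 members over all genes, and edgeR without TG 2 called 5, 3, 11, 6 and 2.

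The camera adjusted p was 9.50e-05 for duct cells, 0.00304 for Schwann cells, 0.00304 for matrix, 0.0260 for stellate cells and 0.0322 for endothelial cells. With an estimated correlation it was 0.776, 0.776, 0.838, 0.838 and 0.838 (unadjusted 0.118, 0.168, 0.419, 0.429 and 0.431). At the preset correlation the duct and Schwann lists stayed past the threshold whichever library was left out. Matrix genes lost the call without TG 1 (0.149), stellate genes without WT 1 (0.248) or TG 1 (0.350), and endothelial genes without WT 1 (0.0670), while without WT 3 (0.708) or TG 3 (0.752) the endothelial direction was reversed. With the acinar covariate the adjusted p was 0.0537 for stellate-cell and fibroblast markers and 0.504 for endothelial-cell markers.

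By camera with its preset correlation, oxidative stress, respiratory chain and clock genes fell as lists and hypoxia genes rose. Of 20 oxidative stress genes 15 were lower, with the metallothioneins Mt1 at 610 ± 461 CPM in TG and 1694 ± 663 CPM in WT and Mt2 at 452 ± 421 and 1267 ± 489 CPM (SD, n = 3). Of 30 respiratory chain genes 24 were lower, but Ndufa1, a complex I subunit, was the 1 past the threshold when adjusted over the list alone and it was higher, with a log2 fold change of 0.73 (SE 0.14). Of 15 clock genes 12 were lower, among them Tef and Bhlhe41 with log2 fold changes of -0.53 (SE 0.18) and -0.46 (SE 0.16). Of 16 hypoxia genes 14 were higher, with Egln3, an oxygen-sensing prolyl hydroxylase, at 46.8, 1.98 and 9.55 CPM in TG 1, TG 2 and TG 3 and 1.38 ± 0.261 CPM in WT. Over all genes the edgeR adjusted p was 0.203 for Mt1, 0.238 for Mt2, 0.272 for Tef, 0.277 for Bhlhe41 and 0.238 for Egln3. No oxidative stress, clock or hypoxia gene passed when adjusted over its list alone (smallest 0.0520, 0.169 and 0.106). Over all genes 0 members of the 4 lists passed in edgeR or limma-voom. At an unadjusted p under 0.05 edgeR had 6 oxidative stress, 1 respiratory chain, 3 clock and 4 hypoxia genes. Among all genes 2271 of 16072 had such a p, so the respiratory chain lay below that share and the clock little above it. In the order of the lists DESeq2 called 3, 1, 0 and 2 members, and edgeR without TG 2 called 5, 5, 3 and 4. The median gene lay -0.33, -0.14 and 0.02 log2 units from the WT level of its table in TG 1, TG 2 and TG 3 for oxidative stress, with WT 1 and WT 2 at -0.16 and 0.16. In TG 3 the median thus lay near 0, although Mt1 and Mt2 were at 205 and 79.5 CPM there against 1083 and 794 CPM in WT 3. It lay at -0.30, 0.15 and -0.32 for the respiratory chain, where TG 2 went the other way, at -0.20, -0.28 and -0.23 for the clock and at 1.65, 0.19 and -0.11 for hypoxia, although Egln3 was higher in TG 3 than in WT 3 (1.18 CPM). The camera adjusted p was 0.0322 for oxidative stress, 0.0277 for the respiratory chain, 0.0322 for the clock and 0.0322 for hypoxia. With an estimated correlation it was 0.776, 0.838, 0.776 and 0.838 (unadjusted 0.214, 0.467, 0.0774 and 0.440). At the preset correlation, calls were lost without WT 2 (0.093) or TG 1 (0.194) for oxidative stress. For the respiratory chain they were lost without WT 3 (0.146), TG 1 (0.465) or TG 3 (0.170). They were also lost without WT 1 (0.0670) or TG 2 (0.164) for the clock, and without WT 1 (0.0670), WT 2 (0.126) or TG 1 (0.585) for hypoxia. With the acinar covariate that of the circadian clock was 0.0523.

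**Figure D3:**
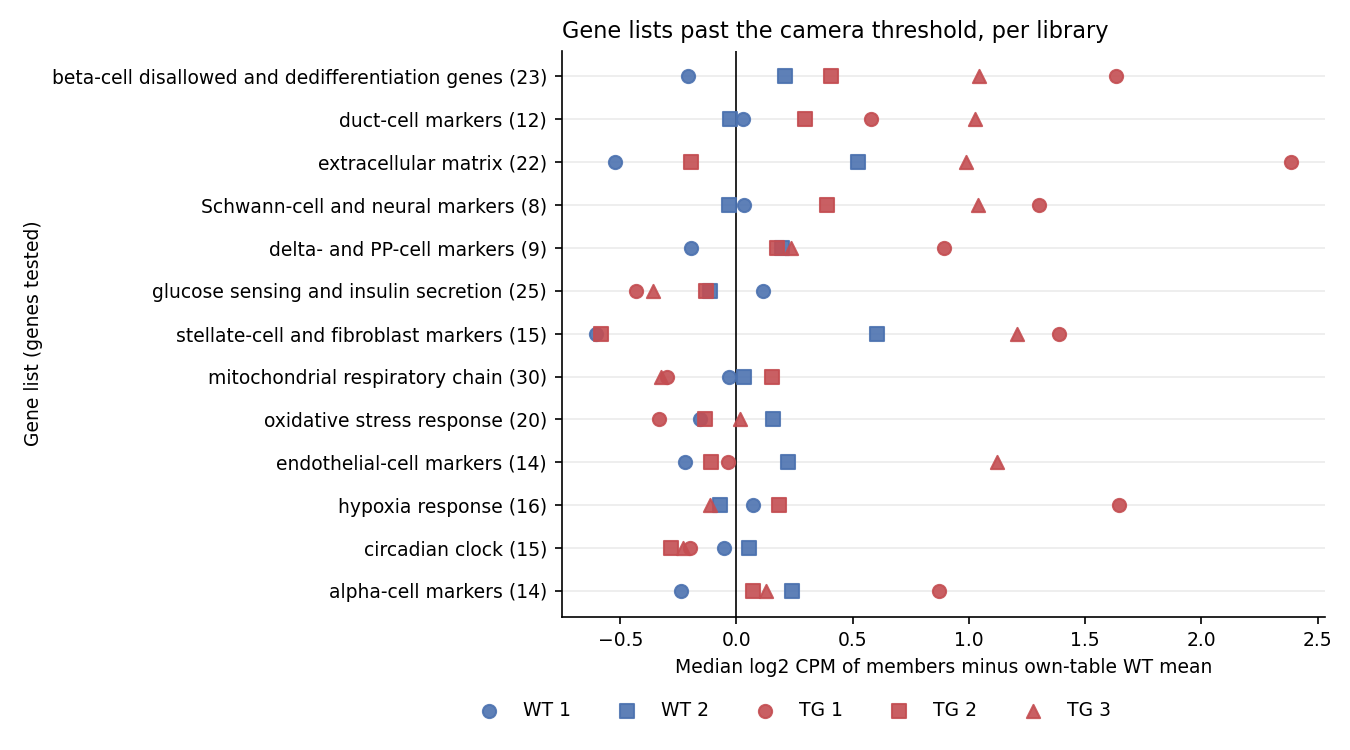
Median over the members of each list past the camera threshold of log2 CPM minus the mean log2 CPM of the WT libraries of the same table, per library; WT 3 is the sole WT library of its table and defines 0. The disallowed and dedifferentiation list lies above 0 in all 3 TG libraries (1.63, 0.41 and 1.04), and for matrix genes TG 2 lies at -0.19.

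In all, 13 of 29 tested lists passed camera with its preset correlation, 9 higher and 4 lower. With an estimated correlation 0 passed (smallest adjusted p 0.776). With fry, a test that does not compare a list with other genes, 0 passed (0.196). Other splits of the 6 libraries gave up to 16 lists past camera at the preset correlation. A call at that setting thus does not set the genotypes apart from other groupings. At that setting 5 lists were higher without TG 1, and 2 were lower without WT 1. The remaining 16 lists did not pass, with camera adjusted p of 0.0562 for compensation and proliferation regulators, 0.0636 for NF-kB signalling, 0.0637 for glycolysis and 0.0787 for immediate-early genes. It was 0.242 for apoptosis, acinar cells and cytosolic ribosomal proteins alike, 0.314 for myeloid cells, 0.512 for ER stress and 0.529 for exocytosis. The others had 0.763 for reported miR-203 targets, 0.788 for lipid synthesis, 0.922 for interferon, mitotic and lymphocyte genes, and 0.377 for the beta-cell hormone list given above. Adjusted over the list alone, Ccl2, Il6 and Vcam1 were among 5 NF-kB genes past the threshold and higher, and Nfkb2 was lower. Among lymphocyte genes, likewise adjusted, Cd79a, Ighm and Igkc were lower and Ccr7 higher. Over all genes 0 members of both lists passed in edgeR or limma-voom, with 9 NF-kB and 4 lymphocyte genes at an unadjusted p under 0.05 in edgeR, against 4 and 2 called by DESeq2 and 6 and 2 by edgeR without TG 2. Of the 12 reported miR-203 targets tested, 7 were higher and 5 lower, with a median log2 fold change of 0.05. Only 4 fat-cell and 3 red-cell genes were tested, of which 2 and 3 were higher.

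The effect of the genotype was compared between the tables, since the second held Xist-rich libraries. Interferon genes had a median TG effect of -0.36 in the first table and 0.81 in the second, endothelial genes -0.06 and 1.12, acinar genes -0.14 and 0.74, and hypoxia genes 0.91 and -0.11. The disallowed and dedifferentiation list had similar medians of 1.07 and 1.04. The camera test of the interaction passed for 9 lists, with adjusted p of 9.28e-10 for interferon, 2.13e-08 for endothelial, 1.09e-05 for acinar and 0.00603 for hypoxia genes, and 0 lists passed with an estimated correlation, every adjusted p being 0.922 or higher. For single genes the edgeR interaction called 0 at a Benjamini-Hochberg adjusted p under 0.05, with 366 at an unadjusted p under 0.05, and it called 67 larger and 70 smaller effects in the second table without the low-count filter. Without TG 1 it called 3 larger and 6 smaller, and without WT 2 it called 3 smaller. No other tool was run on the interaction.

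To ask whether genes that miR-203-3p can pair with were lower in TG, tested genes with and without a site in the 3' UTR were compared. Among the 10 lower genes named above, 4 carried the site CATTTCA. They were Pdx1 at 147275790 to 147275796 on chromosome 5, Srgap1 at 121783704 to 121783710 on chromosome 10, Slc35b4 at 2 places on chromosome 6, and Wdr7 at 3 places on chromosome 18, of which the site at 63988226 to 63988232 was an 8-mer. None of the 10 higher genes did, and 17.3% of all tested genes with a 3' UTR carried it. The 10 lower genes also had longer 3' UTRs, with a median of 2262.5 bases (741 to 5000) against 682 bases (68 to 2473) in the 10 higher genes, and a longer sequence holds more sites. Over all of these genes, the mean log2 fold change was 0.10 for the 2395 with the site and 0.12 for the 11456 without, a difference of -0.0171. Of the 210 rearrangements of the 7 bases, 17 gave a difference as low, a one-sided permutation p of 0.0810, and the site ranked 1319 of 15861 7-mers. The camera p of the site genes was 0.557, and 0.678 with an estimated correlation. Without TG 1 the difference was -0.0265 and 2 of 210 were as low (permutation p = 0.00952). Counting any 6-mer or the shortest 3' UTR gave 0.00751 and 0.00532.

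**Figure D4:**
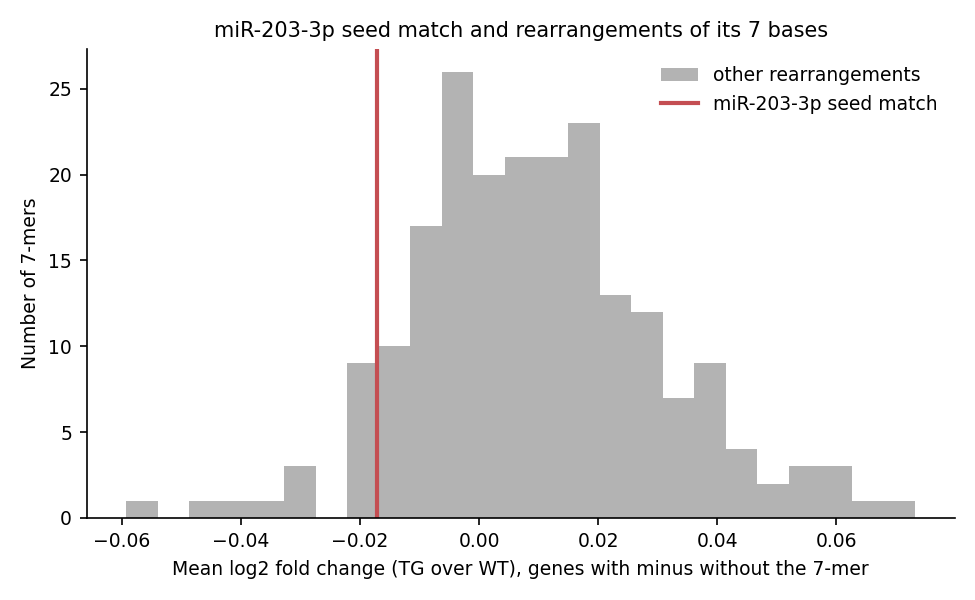
Distribution over the 210 rearrangements of CATTTCA of the mean log2 fold change (TG over WT) of genes with the 7-mer in the 3' UTR minus that of genes without; grey bars count the other rearrangements and the red line marks the miR-203-3p site at -0.0171. Of the 210, 17 lie at or below the line.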

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

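The tests chosen only after the result was seen were those of TG 2 as a WT library, of fewer beta cells, of both sex explanations, of the carry-over of TG 2 or TG 1 RNA into WT 1, and the Mir203 tests of TG 2 as a mixed sample and of WT 1 as a TG library, while the 80% and 50% bounds for a mixture were set beforehand.

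TG 2 lay closer to the WT libraries than TG 1 and TG 3 did, with Ins2 at 13.7% of its counts. A wrong genotype label is argued against by its 6.51 CPM at the Mir203 locus, above the interval of every WT library. Fewer beta cells in TG 1 and TG 3 would lower transcripts made only in beta cells alike. The mean log2 changes of 10 beta-cell transcripts spanned 6.57, from -6.29 (Ucn3) to 0.28 (Nkx6-1), against 0.93 between WT 1 and WT 2. The 10 were chosen after the result was seen. Whether other islet cells also make them was not tested, so the span cannot decide the question. Ucn3 and Mafa (-6.04) fell far more than Ins1 (-1.37), Ins2 (-2.17) and Slc2a2 (-2.36), so 1 common factor does not describe them. A part played by fewer beta cells stays open, since markers of other endocrine cells rose by camera with its preset correlation. WT RNA mixed with RNA like that of TG 1 is argued against by the same locus: in 90 genes at least 4 times above WT in TG 1 and TG 3, TG 2 held a median share of 12.8% of the TG 1 excess, which with WT 1 RNA gives at most 3.39 CPM, below the interval of TG 2, although 60% of the genes lay within 2 times of that share (80% was set for a mixture, 50% against it). A milder response to the transgene may hold as a hypothesis and was not tested separately.

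WT 3 and TG 3, labelled male, had Xist reads and hardly any Y-linked reads, with Xist at least 1850 times its highest level in the first table. Female origin of both libraries may account for this, since the 4 Y-linked genes reached at most 0.304% of their first-table median (upper 95% Poisson bound 0.494%). Male libraries mixed with RNA from females are argued against by the same value, because a mixture would keep a larger Y-linked share. The table and the sex-linked pattern coincide, so effects of the table and of sex cannot be told apart here.

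The library labelled WT 1 had 39 Mir203-locus reads where WT 2 and WT 3 had 0. A TG library under a WT label is argued against by its Mir203 level, whose upper bound of 2.88 CPM lies below the lowest bound of a TG library (5.06 CPM), although WT 1 lay closer to TG 2 than to WT 2 (chi-square per degree of freedom 31.6 and 42.4). Carry-over of TG 1 RNA, or TG 1 reads misassigned in sequencing, is argued against because Aldh1a3, Gast and Cck reached at most 5.36% of the level that a 35.6% share of TG 1 would bring. Carry-over of TG 2 RNA, or its misassigned reads, could account for the 255 genes higher in TG 1 and TG 3 than in WT 3. Their median log2 ratio of WT 1 to WT 2 was 0.370 (95% bootstrap interval 0.235 to 0.490). This interval and the next resampled genes, which are not replicates, and do not measure the spread between libraries. A share of 32.3% (22.2% to 46.1% from counting error) predicts 0.379. For the 296 lower genes the median was -0.005 (-0.06 to 0.05), where that share predicts -0.07. Only the lower bound of the share, at -0.05, lies inside that interval. That allowance for counting error was added after the lower genes had met the bound first set, and the genes were first chosen on TG 2 too (182 genes, 0.576), so the evidence on TG 2 RNA stays divided, and expression of Mir203 by the WT 1 islets themselves, with 0 reads in WT 2 and WT 3, was not tested and stays open.

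In 9 lists the TG effect differed between the tables by camera on the interaction, and with an estimated correlation every adjusted p was 0.922 or higher. The difference of the median log2 effect, second minus first table, was 1.17 for interferon response, 1.18 for endothelial markers, 0.88 for acinar markers, 0.94 for myeloid markers, 0.68 for duct markers, 0.64 for lymphocyte markers, -0.73 for ER stress, -0.82 for glycolysis and -1.03 for hypoxia. The second table has 1 library of each genotype.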

How the results depend on the processing

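Voom with library weights and the bias-adjusted fit without the low-count filter were chosen after the data were seen. Of the 17 alternatives for 80 named genes, none reversed a gene it tested except Iapp. Its log2 fold change was 0.05 without WT 1 and 0.11 without TG 1 (leave-one-out range -0.55 to 0.11). Many of the 80 were chosen by smallest p in these data, which makes a reversal unlikely. The 80 did not include Nkx6-1, Sox9, Npy, Nts, Cartpt, Fgb, Cpb2, Alb or the NF-kB and lymphocyte genes named above. Cdh19 was not tested without TG 1, nor Cdh19 and Clrn3 at a CPM of at least 1 in 3 libraries. Against 0 genes called in edgeR (1498 higher and 773 lower at an unadjusted p under 0.05), DESeq2 called 616 higher and 136 lower, no low-count filter 1300 and 372, and voom with library weights 699 and 275; the cause was not tested, but the bias-adjusted fit on the same unfiltered genes called 0. Leave-one-out fits called 0 to 1461 higher and 0 to 727 lower, the highest without TG 2. All other alternatives called 0. The Mir203 locus log2 fold change passed with no low-count filter (3.45) and with library weights (5.99), and ran from 2.59 without WT 3 to 10.27 without WT 1. Lists past camera (9 higher, 4 lower) numbered 5 to 11 and 2 to 6 in leave-one-out fits, and 0 and 0 with an estimated correlation or fry. The endothelial list reversed with the first table only (adjusted p 0.792) and without WT 3 (0.708) or TG 3 (0.752), with a leave-one-out range of 0.000675 to 0.752; that list depends on the second table. With the acinar covariate 4 of the 13 lists lost their call (stellate 0.0537, endothelial 0.504, clock and alpha-cell 0.0523). The interaction called 67 larger and 70 smaller effects with no filter, and 0 to 3 and 0 to 6 in leave-one-out fits. The miR-203-3p site difference of -0.0171 reversed with any 6-mer (0.00751) and the shortest 3' UTR (0.00532), ranged from -0.0404 to -0.00704 in leave-one-out fits, and passed only without TG 1 (-0.0265); the cause was not tested. No paired analysis was possible because the labels share no replicate numbers between genotypes. Depth limits genes near the floor of 3 counts, such as Mir203 in WT 2 and WT 3 and Clrn3 in WT.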

Other observations

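The tests chosen only after the result was seen were the 2 added gene lists below and, for the site shares, the comparison with other splits of the libraries and all alternatives; the site-share test itself was added after the planned test of site genes had missed its threshold and after the site counts of the named genes were known, but before its own value was.

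Of 19 genes of gut and nerve peptides 14 were tested, and all 14 had a fitted log2 fold change above 0, with a median of 1.81. In edgeR 9 of them had an unadjusted p under 0.05 and 0 passed the threshold, as in limma-voom, while DESeq2 and edgeR without TG 2 called 7 each. Single TG libraries lay below WT, as for Npy with 5.98 CPM in TG 3 and 7.27 CPM in WT 3. Besides Gast and Cck, Nts (neurotensin) was at 8.62, 2.42 and 1.25 CPM in TG 1, TG 2 and TG 3 and at 0.38, 0.18 and 0.09 CPM in WT 1, WT 2 and WT 3. Cartpt was at 15.1, 2.18 and 18.4 CPM in the TG libraries and at 1.57, 0.84 and 0.88 CPM in the WT libraries. Plasma proteins made mainly by liver were the other group, with 15 of 18 tested genes above 0 and a median of 1.23. Of these, 6 higher genes had an unadjusted p under 0.05 and 0 passed in edgeR or limma-voom, while DESeq2 and edgeR without TG 2 called 4 each. Fgb (fibrinogen beta chain) was at 227, 55.7 and 115 CPM in the TG libraries against 28.9, 7.08 and 11.6 CPM in the WT libraries, and Cpb2 at 188, 63.4 and 235 CPM against 21.5, 5.76 and 2.76 CPM. Alb (albumin), a leading liver transcript, went the other way, at 77.3 CPM in WT 3, 37.2 CPM in TG 3 and under 1 CPM in the first table's libraries. Both groups were drawn up from the genes of these data, so their counts describe them and are no test.

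Direct repression by miR-203-3p was examined as a hypothesis through the share of site genes. Among genes lower in TG at an unadjusted p under 0.05, 150 of 702 (21.4%) had the site, and among genes higher 235 of 1412 (16.6%), a difference of 4.72 percentage points. Of the 210 rearrangements 1, the site itself, gave a difference as large (0.476%, the smallest share possible), which may reflect direct repression of some of the lower genes. It stands beside the planned test, in which the mean difference of site genes missed its threshold (permutation p = 0.0810), and the 20 named genes that prompted it are among those counted. The difference also depended on WT 1, without which it was 0.527 points and 25 of 210 were as large, and on the table term, without which it was 2.46 points and 13 of 210 were as large. Without TG 2 it was 1.03 points and 3 of 210 were as large, and without WT 3 or TG 3 it was 8.51 and 8.72 points. The median 3' UTR was 1274 bases in the lower and 1207 bases in the higher genes. Some other splits of the 6 libraries also gave a small share of rearrangements as large. It was 1.905% for WT 1, WT 3 and TG 2 against the rest and 2.857% for WT 1, TG 1 and TG 3 against the rest. Every remaining split but the real one had 7.14% or more.

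The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05, and 4 of them put both libraries of the second table on 1 side, unlike the real split. All 10 splits gave as many genes past the threshold as the real one (0, highest other 0). The genes at an unadjusted p under 0.05 numbered 2271 in the real split and at most 2288 in another, and 2 splits reached as many. Every count of splits as large, here and below, includes the real split. Lists past camera numbered 13 and at most 16, with 6 splits as high. The site difference was -0.0171, the largest in another split -0.0477, and 6 splits were as large in size. The difference in site shares was 4.72 points, at most 11.8 in another split, and 6 splits were as large in size. Among the 6 splits that part the second table, the highest other values were 0, 2288, 15, -0.0326 and 10.7 in the same order. Of these 6 splits, 6, 2, 4, 3 and 3 were as large. The split with 2288 genes set WT 1, WT 3 and TG 2 against WT 2, TG 1 and TG 3, and so placed TG 2 with WT libraries.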
